A study of Mus musculus with 3 samples.

How the data were processed

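Total RNA of muscle from 10 male mice per group was pooled, labelled with Cy3 and hybridised to 1 single-colour Agilent whole-genome array per group, per the labels' protocols. The 3 groups were taken from the labels, and all 3 arrays lay on 1 slide and in 1 scan per the file headers, so slide and scan could not differ between groups, while the position on the slide did. The deposited scanner files hold intensity values made by Agilent Feature Extraction 9.5, per the submitters' processing notes: a processed signal, background-subtracted and detrended within the array, with its error, the mean spot and median local background intensity, and flags per spot. The authors' value table holds log2 values of 13683 spots, 31.5% of the 43379 that are not controls. Set against the scanner files, its differences between arrays were within 0.01 of the log2 signal differences plus a constant for 56.4%, 56.6% and 55.8% of spots in the 3 comparisons, with r of 0.77, 0.82 and 0.71. The medians of its columns were 0.008, -0.005 and 0.010. The direction is therefore that of the signal and the scale is log2, while the value on which each probe was centred stays unknown, so only differences between its columns were used. A centre per probe cancels in such differences, so it does not account for the spots beyond 0.01. What changed these spots stays unknown and enters every result with the authors' values.

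Control spots and spots with an outlier flag were left out, spots of one probe were averaged, and 41169 probes remained. Values are log2 of the processed signal minus the array's 75th percentile over these probes. Probes were named through the accession in the files and a RefSeq gene table of assembly GRCm38.p6, used for names alone: 22948 by accession, 6658 by symbol and 3109 by an older symbol, while 8454 kept the file's name. A gene was represented by its brightest unflagged probe, giving 27665 genes, of which 18364 had a gene symbol. Where genes past the 2-fold rule had several measured probes, 8 of 157, 14 of 171 and 14 of 86 in the 3 comparisons had a probe of opposite sign.

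With 1 array per group, genes were counted by size: at least 2-fold and well above background on both arrays. A gene well above background on 1 array only has a bound, the bright value against the higher of the dim array's lowest signal well above background and the dim probe's own signal, and was counted apart. The lowest such signals were 6.45, 5.78 and 6.26. The errors at hand were technical. The scanner software's error had a median of 10.0% of the signal, the multiplicative part set in the file headers, which gave 0.20 per log2 ratio. The 245 probes spotted 10 times per array had a median SD of 0.066, 0.062 and 0.058 log2 between spots, over 166, 178 and 165 probes with at least 8 spots well above background.

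The 39 gene lists were fixed before the data were examined, as were the rule for named genes, the comparisons and the alternatives apart from those said to be added. A list's median log2 ratio was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression, and its random range is the central 95%. This describes these arrays and is no test, since genes of a list vary together. Lists shared genes, and at least 5 measured members were needed. Named genes were, per comparison, the 8 largest and 8 smallest ratios among genes with a symbol that passed the 2-fold rule with all measured probes of the same sign, up to 3 members of each list farthest from 0 that passed it, and the 3 farthest members of each list outside its random range. Of the genes this rule gives, a part is named in the text. A result withheld for evaluation is not reported here. A further 11 lists of other tissues were written after a first look at the data. The kidney list left out the genes seen by then. Other added lists share genes with the fixed lists, such as 14 of 23 for bone and cartilage cells and 6 of 20 for brown fat. Extremes remained in some of them: the largest ratio in the brown fat list, Chlorella against normal food in swimming, was 3.05, that of Zic1. But the brown fat list held neither Ucp1 nor Cidea, and the bone and cartilage list neither Mepe nor Ibsp.

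Alternatives were quantile normalization, cyclic loess, median centring, the percentile over probes well above background, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, the mean over probes, and the authors' value table. For counts the 95% limit of the scanner error was also required, for lists the mean and members at their bound were tried, and for the correlation 2 different probes. Ranges of list medians over the alternative settings cover the 9 settings named first and leave out members at their bound. Median centring moved the median of all genes by -0.15 in swimming against nonswimming and by 0.13 in Chlorella against normal food, and leaving out the filter moved it by -0.10 and 0.12. The steps were tested on simulated data for swimming against nonswimming over 15661 genes. With 200 genes changed by a log2 of 1.5, 99.5% were recovered and 8 unchanged genes were called, and with a log2 of 3, 100.0% and 12. Of 200 unchanged lists of 25 genes 2.0% lay outside their random range, and of 200 lists shifted by 0.3, 100.0% did. These simulated arrays held spot error alone, with no difference between mice or pools, and list members were drawn independently. They check the steps and do not measure the error of the real comparisons. Chance values of shared arrays came from 100 simulated sets of unchanged arrays with the spot errors. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.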

Results

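The series profiled gene expression in muscle of male mice after 14 days with or without swimming and with or without Chlorella, a unicellular green alga, in the food. The labels give 3 groups: mice on normal food that did not swim, mice on normal food that swam, and swimming mice whose food held 0.5% Chlorella powder. Which muscle was taken is not given in the sources used here. Each group was measured on 1 single-colour array with RNA pooled from 10 mice. Of 41169 probes, 23841 were well above background on the nonswimming array, 24857 on the swimming array and 23448 on the Chlorella array. No probe was saturated. The 75th percentile of the processed signal was 285.9, 295.0 and 237.8 intensity units on these arrays. With 1 array per group there was no replicate, so no test between groups was possible, and the differences below have no replicate check. The error given beside a log2 ratio is the scanner software's error of the 2 spots and holds no difference between mice. The number of arrays limits the precision.

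The first comparison asked how muscle of swimming mice differed from muscle of nonswimming mice on normal food. Neutrophil, B cell and erythrocyte genes were far higher on the swimming array. Of 18 measured neutrophil genes, 17 were at least 2-fold higher and none was lower by that size, with a median log2 ratio of 3.57. The B cell and immunoglobulin list had 13 of 16 genes at least 2-fold higher and a median of 2.46, and the erythrocyte list had 13 of 15 and a median of 1.98. Genes of the cell cycle (23 of 37, median 1.65) and of adipocytes (19 of 32, median 1.22) were also higher on the swimming array. In the other direction, keratinocyte genes of the skin had a median of -1.25, with 5 of 9 at least 2-fold lower. Over the alternative settings the neutrophil median ranged from 1.72 to 3.69, the B cell one from 0.88 to 2.93, the erythrocyte one from 1.47 to 2.93, the cell cycle one from 0.88 to 1.68 and the keratinocyte one from -1.40 to -0.24, and each stayed outside its random range in every setting that could rank it.

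Among the genes the naming rule allows, the largest log2 ratio was that of Prg2, which encodes the major basic protein of eosinophil granules (4.54 ± 0.20). Its probe lies on chromosome 2 from 84826358 to 84826417 in the coordinates of the scanner files, whose genome build is not given in the sources used here. Prg3 and Epx, also eosinophil granule genes, had ratios of 4.34 ± 0.35 and 4.31 ± 0.29. Camp, the antimicrobial peptide cathelicidin of neutrophils, had a ratio of 4.51 ± 0.20, and S100a8, a subunit of calprotectin, one of 4.43 ± 0.20. The signal of S100a9, the partner subunit, was 3502 on the nonswimming array and 61080 on the swimming array. Spib, a transcription factor of B cells, had a ratio of 4.42 ± 0.34, Pou2af1, a B cell coactivator, 4.02 ± 0.23, and Ms4a1, which encodes CD20, 3.91 ± 0.24. S100g, a calcium-binding protein of gut and kidney, had a ratio of 4.27 ± 0.25. Of erythroid genes, Hemgn had a ratio of 4.01 ± 0.23 and Rhd one of 3.73 ± 0.22. Mki67 (3.31 ± 0.21), Top2a (2.94 ± 0.34) and Ccnb2 (2.91 ± 0.20), all genes of dividing cells, led the cell cycle list. Prg3, Epx, Spib and Top2a were dim on the nonswimming array, with signals of 7.608, 9.241, 8.205 and 7.655. The lowest signal well above background there was 6.45, so the size of these 4 ratios is uncertain. The bone genes Mepe and Bglap had ratios of 2.26 and 2.20, although the median of the tendon, cartilage and bone list (-0.08) lay inside its random range.

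Fat genes were led by Ucp1, the uncoupling protein of brown fat (4.25 ± 0.20). Fatty acid synthesis genes were higher as well: Elovl6, a fatty acid elongase, had a ratio of 3.75 ± 0.20, Acaca, acetyl-CoA carboxylase, 2.94 ± 0.20, and Acly, ATP citrate lyase, 2.81 ± 0.20. The cholesterol and fatty acid synthesis list had 8 of 41 genes at least 2-fold higher and a median of 0.25, above the range of -0.13 to 0.04 of its random lists. In the fatty acid oxidation list 3 of 41 genes were at least 2-fold higher and none was lower by that size: Cidea, a lipid droplet protein (2.80 ± 0.20), Angptl4 (1.45 ± 0.20) and Plin2 (1.18 ± 0.20). The median of that whole list was -0.18, below its random range of -0.14 to 0.03 except with the authors' values, and Fabp3 and Pdk4 had ratios of -0.55 and -0.51. Adipocyte markers were higher beside these fat genes, as given above.

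Contractile genes differed in both directions. In the slow-fibre list 7 of 22 genes were at least 2-fold higher and 2 were lower, with a median of 0.01 inside its random range. Myh7, the myosin heavy chain of slow fibres and heart, had a ratio of 1.69 ± 0.20, Myh6 one of 1.84 ± 0.20 and Sln, sarcolipin, an inhibitor of the calcium pump, one of 2.22 ± 0.20. None of 22 fast-fibre genes differed 2-fold (median -0.14). Both medians changed sign under another scaling, the slow-fibre one with cyclic loess and with median centring, which moved all genes alike by -0.15, and the fast-fibre one with quantile normalization. The slow-fibre median reached 0.63 under the alternative settings and left its random range with quantile normalization, the mean over probes and the authors' values. Lists with small medians below their random ranges were those of heat shock and protein folding (-0.21), the circadian clock (-0.26), endothelial cells and pericytes (-0.23), the citric acid cycle (-0.19), and collagen and extracellular matrix (-0.17). Glycolysis (-0.15), ubiquitin-proteasome and atrophy genes (-0.15), hypoxia (-0.16) and glucocorticoid-responsive genes (-0.16) also lay below theirs, but not under every setting. The glycolysis call was lost with cyclic loess and the authors' values, the hypoxia call with the mean over probes and the authors' values, and the glucocorticoid call with normexp. The atrophy call was lost with normexp, the stricter filter, the mean over probes and the authors' values. Per1, a clock gene, had a ratio of -1.41 ± 0.20, Fbxo32, the atrophy ubiquitin ligase atrogin-1, -1.10 ± 0.20, and Socs3, a cytokine signalling inhibitor, -1.69 ± 0.20. Ribosomal protein genes had a median of 0.20 and the antioxidant list one of 0.12, both above their random ranges, and the antioxidant median was -0.03 after median centring and lay inside its range with the authors' values.

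Immune signalling lists had smaller medians than the neutrophil, B cell and erythrocyte lists. Cytokines and chemokines had 7 of 38 genes at least 2-fold higher, 1 lower and a median of 0.14, and their receptors had 6 of 40, none lower and a median of 0.14, both above their random ranges, with the platelet chemokine Ppbp at 4.07 ± 0.21 and lymphotoxin beta, Ltb, at 2.62 ± 0.20. With median centring these 2 medians were -0.01 and -0.02, still above their ranges, and with quantile normalization, normexp, cyclic loess and no filter the cytokine median lay inside its range. The receptor median lay inside its range with the stricter filter and the authors' values. MHC class I genes had a median of 0.10, above their random range, and still above it at -0.06 after median centring, but inside it with the authors' values. Macrophage and dendritic cell genes (median 0.02), MHC class II genes (0.05), interferon-stimulated genes (0.07), T and NK cell genes (0.22) and Toll-like receptor genes (-0.02) lay inside theirs. The T and NK cell call held in only 3 of 9 alternative settings, whose medians ranged from 0.06 to 0.64, and with genes at their bound the median was 0.67, above its random range. With the mean over probes the interferon-stimulated median also left its range. Complement and acute-phase genes had 6 of 28 at least 2-fold higher and none lower by that size, but a median of -0.13, inside its random range except with quantile normalization and cyclic loess.

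Under the same rule the lowest ratios belonged to epidermal genes. Lor, the cornified envelope protein loricrin, had a ratio of -4.84 ± 0.26, Krt5 one of -4.52 ± 0.25 and Krt15 one of -4.44 ± 0.26. The Lor probe lies on chromosome 3 from 92114279 to 92114338 in the same coordinates. Dmkn, dermokine, had a ratio of -3.34 ± 0.35. Klra21, Mob3b, Gas7 and Psapl1 followed, between -2.83 and -2.25. Of the 2 probes of Gas7, the dimmer one had a ratio of only -0.005.

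In all, 805 of 15661 genes measured on both arrays were at least 2-fold higher on the swimming array and 167 were at least 2-fold lower. A further 390 genes were well above background only on the swimming array and at least 2-fold higher by their bound, and 242 were bounded the other way. Simulated arrays that differed only by spot error gave a mean of 2.1 genes higher and 1.8 lower. Of 39 gene lists, 22 lay outside their random ranges, where 1.95 would if list members varied like randomly drawn genes. Genes of a list vary together, so 1.95 is too low a chance value and the count is no test. Without the genes of the cell type, cell cycle and other-tissue lists, an alternative chosen after seeing the data, 660 genes were higher and 154 lower. The 590 listed genes left out did not include Prg2, Prg3, Epx or S100g, so the 660 still hold these. The counts ranged from 387 to 2104 higher and from 42 to 1255 lower under the alternative settings, and the higher share of 82.8% was 70.9% after median centring, 62.6% without the filter on dim probes and 90.2% with normexp.

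**Figure D1:**
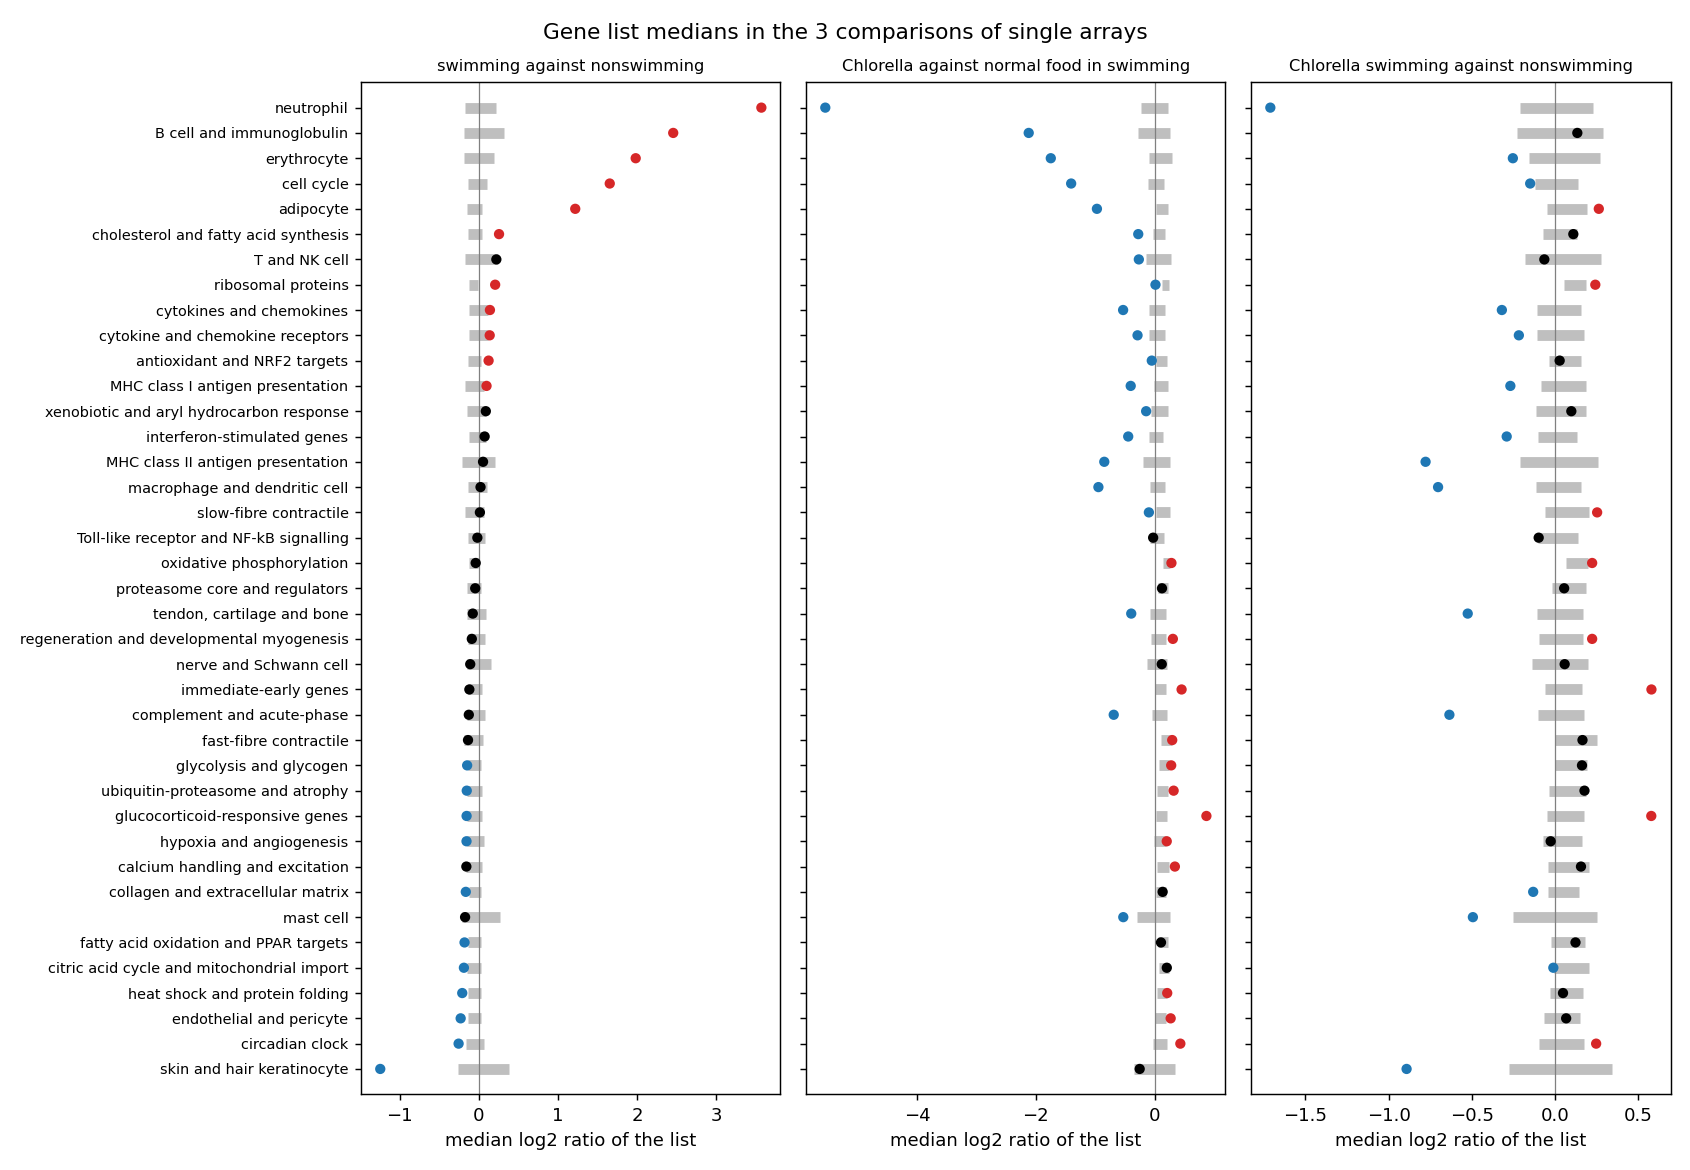
Median log2 ratio (horizontal axis) of each of the 39 gene lists (vertical axis) in the 3 comparisons. Grey bars span the central 95% of 10000 random lists matched on mean expression, and points are red above it, blue below it and black inside it, with a separate scale in each panel. The neutrophil list sits at 3.57 in the first comparison and at -5.55 in the second.

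The second comparison set swimming mice fed Chlorella against swimming mice on normal food. Neutrophil, B cell and erythrocyte genes were far lower on the Chlorella array, and genes that respond to glucocorticoids or to acute stimuli were higher. The neutrophil list had 13 of 14 measured genes at least 2-fold lower and a median log2 ratio of -5.55. B cell (11 of 14, median -2.12), erythrocyte (8 of 10, median -1.75) and cell cycle genes (21 of 34, median -1.40) were lower too. Of 35 measured glucocorticoid-responsive genes, 17 were at least 2-fold higher and 1 was lower, with a median of 0.87 against a random range of 0.02 to 0.21. Immediate-early genes had 16 of 37 at least 2-fold higher and 1 lower, with a median of 0.46. Over the alternative settings the neutrophil median ranged from -5.60 to -3.61, the B cell one from -2.65 to -0.60, the erythrocyte one from -3.29 to -1.61, the cell cycle one from -1.84 to -0.92 and the immediate-early one from 0.40 to 0.95, all outside their random ranges. With members at their bound the neutrophil median was -3.40 over 25 genes, also below its random range.

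Under the naming rule the lowest ratio was that of Prg2 (-8.63 ± 0.27), whose signal was 5038 on the swimming array and 10.27 on the Chlorella array. The neutrophil granule genes Camp (-7.53 ± 0.28), Ngp (-7.51 ± 0.30), Ltf, lactoferrin (-7.45 ± 0.24), Mpo, myeloperoxidase (-6.70 ± 0.22), and Ctsg, cathepsin G (-6.61 ± 0.26), followed with S100a8 (-6.82 ± 0.21) and S100a9 (-6.19 ± 0.20). Pou2af1 had a ratio of -4.85 ± 0.29, Cd79b, part of the B cell receptor, -3.87 ± 0.21, and Slc4a1, the anion exchanger of red cells, -4.85 ± 0.21. Bone genes were lower, with Mepe at -3.67 ± 0.22, Ibsp at -3.66 ± 0.22 and Bglap at -3.20 ± 0.20, and the tendon, cartilage and bone list had a median of -0.39, below its random range.

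The immune lists that follow had lower medians too, to a smaller degree. Single members fell further, such as Chil3 at -5.65 ± 0.22 among macrophage genes and Ppbp at -5.43 ± 0.24 among cytokines. In the macrophage and dendritic cell list 13 of 33 genes were at least 2-fold lower and 1 was higher, with a median of -0.95. None of 11 measured MHC class II genes passed the 2-fold rule, but all lay between -0.98 and -0.47, with a median of -0.85 and with H2-Ea at -0.98, Ctss at -0.97 and H2-Aa at -0.96. Complement and acute-phase genes had a median of -0.69, cytokines and chemokines -0.53, mast cell genes -0.53, interferon-stimulated genes -0.44, MHC class I genes -0.40, cytokine receptors -0.29 and T and NK cell genes -0.26, all below their random ranges. Ccr2, a chemokine receptor of monocytes, had a ratio of -1.90 ± 0.24. With normexp background correction the T and NK cell median was 0.07, the mast cell median -0.12 and the tendon, cartilage and bone median -0.04, all inside their random ranges, and the T and NK cell call was also lost with the stricter filter. Over the alternative settings the macrophage median was -0.59 at its nearest to 0, and the cytokine median ranged from -0.60 to -0.23.

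The metallothionein gene Mt2 had a ratio of 2.82 ± 0.20, with a signal of 3473 on the swimming array and 19700 on the Chlorella array, and Mt1 had 2.01 ± 0.20. The Mt2 probe lies on chromosome 8 from 92762515 to 92762574 in the same coordinates. Ddit4, an inhibitor of mTORC1 induced by glucocorticoids, had a ratio of 2.30 ± 0.20. These 3 genes were members of both the glucocorticoid list and the ubiquitin-proteasome and atrophy list, whose median was 0.32 with 6 of 35 genes at least 2-fold higher, inside its random range with the authors' values. Arrdc2 had a ratio of 2.44 ± 0.20. Maff (2.85 ± 0.20), Sik1 (2.25 ± 0.21) and Nr4a2 (2.15 ± 0.20) led the immediate-early genes, and Per1 (1.97 ± 0.20) and Ciart (1.60 ± 0.21) led the circadian clock list, whose median was 0.43. Under the naming rule the largest ratio was that of Zic1, a developmental transcription factor (3.05 ± 0.26), on dim signals of 14.63 and 97.5. Cfap100, Il12rb1, C2cd4b and Slc25a25 had ratios of 2.95, 2.69, 2.53 and 2.52. Of these, Cfap100, Il12rb1 and C2cd4b were dimmer still on the swimming array, with signals of 9.331, 10.09 and 9.957.

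Fat genes were lower on the Chlorella array. The adipocyte list had 11 of 31 genes at least 2-fold lower and a median of -0.97, with Ucp1 at -2.69 ± 0.20 and Adipoq, adiponectin, at -1.40 ± 0.20. Elovl6 and Acly had ratios of -1.66 ± 0.20 and -1.48 ± 0.20, and the cholesterol and fatty acid synthesis list had a median of -0.27. Muscle lists had small medians above their random ranges, at 0.34 for calcium handling, 0.31 for regeneration, 0.28 for oxidative phosphorylation, 0.28 for glycolysis and 0.30 for fast fibres, and the slow-fibre list had a median of -0.10, below its own. That call was kept in 9 of 9 alternative settings, also at 0.04 after median centring, which moved all genes by 0.13. Sln had a ratio of -1.48 ± 0.20 and Myh1, a fast myosin heavy chain, one of 0.70 ± 0.20. With quantile normalization, cyclic loess and the authors' values, the fast-fibre and glycolysis medians lay inside their random ranges.

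Of 15508 genes measured on both arrays, 212 were at least 2-fold higher and 754 at least 2-fold lower on the Chlorella array. Another 168 genes were higher and 417 lower by their bound. Spot error alone gave a mean of 2.4 genes higher and 1.9 lower in simulated arrays. Outside their random ranges lay 32 of 39 lists. Without the cell type, cell cycle and other-tissue lists, an alternative chosen after seeing the data, the counts were 205 and 622, with Prg2 still among the 622. Alternative settings gave 51 to 1233 genes higher and 301 to 1998 lower, and the higher share of 21.9% was 32.8% after median centring, 38.2% without the filter on dim probes and 14.5% with normexp.

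**Figure D2:**
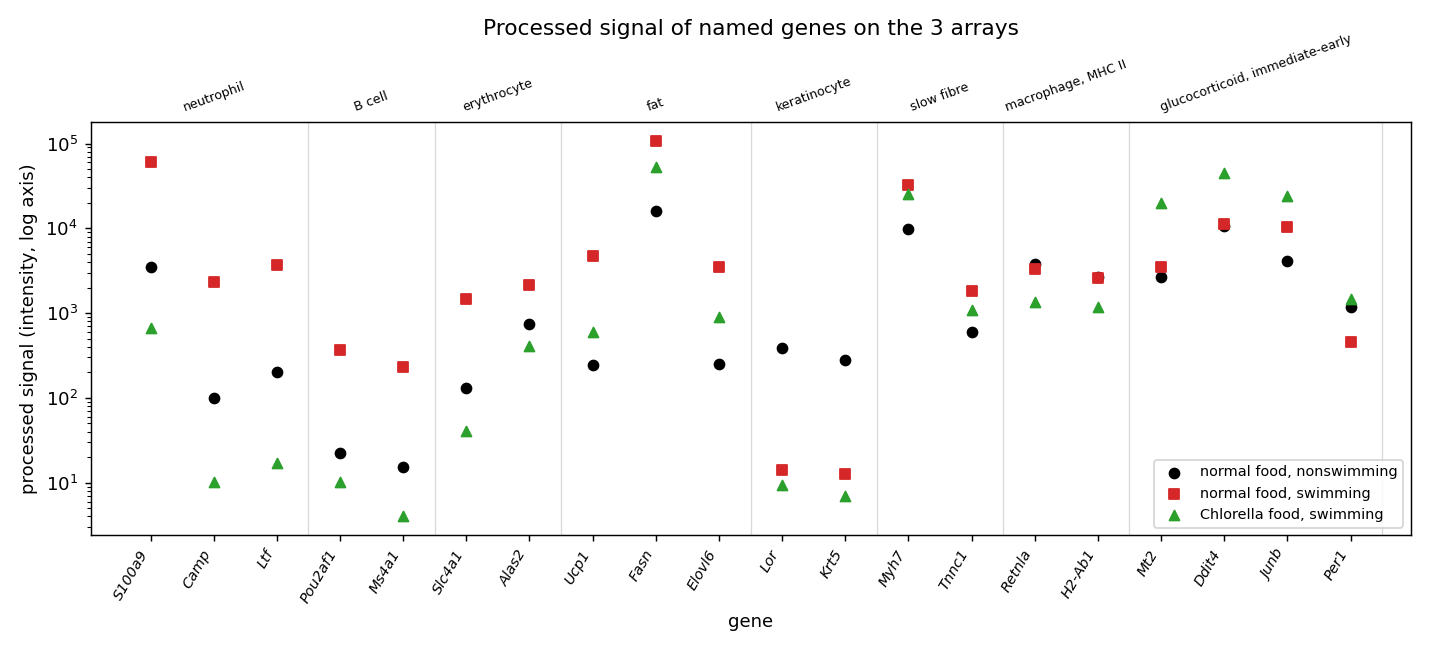
Processed signal (vertical log axis, intensity) of named genes (horizontal axis), with 1 point per array: black circles for nonswimming, red squares for swimming and green triangles for Chlorella swimming. S100a9 stands at 61080 on the swimming array against 3502 and 673.4 on the others, and Mt2 is highest on the Chlorella array at 19700. Camp, Ms4a1, Pou2af1, Lor and Krt5 lie near background where their points are lowest.

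The third comparison set Chlorella-fed swimming mice against nonswimming mice on normal food, and did not use the swimming array on normal food. Immediate-early and glucocorticoid-responsive genes were again higher on the Chlorella array, and genes of macrophages, MHC class II, complement and mast cells were lower. Immediate-early genes had 12 of 37 at least 2-fold higher and 2 lower, with a median of 0.58, and glucocorticoid-responsive genes had 10 of 35 higher and none lower by that size, with a median of 0.58. In the macrophage and dendritic cell list 9 of 32 genes were at least 2-fold lower and none was higher by that size, with a median of -0.70. The median of the MHC class II list was -0.78, with 2 of 11 genes at least 2-fold lower.

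Mt2 (3.15 ± 0.20), Mt1 (2.64 ± 0.20), Ddit4 (2.36 ± 0.20) and the immediate-early genes Junb (2.82 ± 0.20), Maff (2.60 ± 0.20) and Zfp36 (2.36 ± 0.20) all had signals above the 75th percentile of both arrays. The naming rule gave the largest ratio for Tatdn2 (3.44 ± 0.21), a gene of a nuclease-like protein whose probe lies on chromosome 6 from 113871009 to 113871068. Eml2, a microtubule-associated protein, had a ratio of 3.20 ± 0.20, Il12rb1, an interleukin 12 receptor subunit, 2.82 ± 0.32, Zfyve9 2.79 ± 0.21 and Nfasc 2.64 ± 0.29. Il12rb1 and Nfasc were dim on the nonswimming array, with signals of 8.938 and 10.54. The circadian clock list had a median of 0.25, with Per1 at 0.56 and Ciart at 1.06, and lay inside its random range with the authors' values.

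Retnla and Mgl2, genes of alternatively activated macrophages, had ratios of -1.22 ± 0.20 and -1.16 ± 0.21, and Chil3 one of -1.79 ± 0.22. H2-Ea had a ratio of -1.31 ± 0.22, H2-DMb2 -1.06 ± 0.22 and H2-Ab1 -0.91 ± 0.20. Complement and acute-phase genes had a median of -0.64, with C4b at -1.27 ± 0.20. The mast cell list had a median of -0.49 and 4 of 11 genes at least 2-fold lower, among them the proteases Cma1 (-1.40 ± 0.20), Tpsb2 (-1.29 ± 0.21) and Mcpt4 (-1.25 ± 0.20). Cytokines and chemokines had a median of -0.32, interferon-stimulated genes -0.29, MHC class I genes -0.27 and cytokine receptors -0.22, all below their random ranges, with Ccl8 at -1.44 ± 0.20. Over the alternative settings the macrophage median ranged from -0.73 to -0.44, the mast cell one from -0.52 to -0.14 and the cytokine one from -0.34 to -0.04, all below their random ranges. With members at their bound the cytokine median was -0.42 over 38 genes, also below its random range. B cell genes (0.13) and T and NK cell genes (-0.06) lay inside theirs, with signs that changed under some settings, and with the authors' values the B cell median was -0.29, outside its range.

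Neutrophil genes were lower than on the nonswimming array as well, with 9 of 14 at least 2-fold lower, a median of -1.71, and Ngp, Ltf and Ctsg at -3.88, -3.31 and -3.17. Its median ranged from -1.77 to -0.74 over the alternative settings, and that of the skin keratinocyte list from -0.92 to -0.34. The keratinocyte median was -0.89, with Lor at -5.10 ± 0.32 and Krt5 at -5.10 ± 0.34. With members at their bound that median was -1.185 over 12 genes. Tendon, cartilage and bone genes had 9 of 27 at least 2-fold lower and a median of -0.52, with Ibsp at -2.27 ± 0.22 and the cartilage collagen Col9a1 at -2.08 ± 0.27. The collagen and extracellular matrix list had a median of -0.13, with Dcn, decorin, at -0.86 ± 0.20. Endothelial cell and pericyte genes (0.07) and nerve and Schwann cell genes (0.06) lay inside their random ranges, and changed sign with the authors' values.

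Some slow-fibre and lipogenic genes were higher than on the nonswimming array. The slow-fibre list had 5 of 22 genes at least 2-fold higher and a median of 0.25, with Myh6 at 1.69 ± 0.20, Myh7 at 1.66 ± 0.20 and Tnnc1, slow troponin C, at 1.11 ± 0.20. Elovl6 had a ratio of 2.09 ± 0.20, Fasn, fatty acid synthase, 1.98 ± 0.20, Cidea 1.83 ± 0.20 and Acaca 1.73 ± 0.20. The cholesterol and fatty acid synthesis list had 6 of 41 genes at least 2-fold higher, with a median of 0.11 inside its random range, and the adipocyte list had 7 of 31 and a median of 0.26, above its own. With cyclic loess the slow-fibre median lay inside its random range and the cholesterol and fatty acid synthesis median outside.

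In total, 318 of 15336 genes were at least 2-fold higher and 228 at least 2-fold lower, and 179 and 217 more were so by their bound. Simulated spot error gave a mean of 3.2 genes higher and 2.8 lower. Of the 39 lists, 23 lay outside their random ranges. Without the cell type, cell cycle and other-tissue lists, chosen after seeing the data, 301 genes were higher and 186 lower, with Prg2 still among the 186. The counts ranged from 92 to 1395 higher and from 57 to 1266 lower under the alternative settings.

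The swimming and Chlorella log2 ratios were then set against each other over the 15269 genes measured on all 3 arrays. Of 710 genes at least 2-fold higher with swimming, 509 were at least 2-fold lower with Chlorella, where independent lists would share 33.8 and simulated unchanged arrays 0.1. Of 141 genes lower with swimming, 29 were higher with Chlorella, against 1.8 for independent lists and 0.2 in simulated unchanged arrays. Pearson's r across genes was -0.70 and Spearman's rho -0.45, but both ratios hold the swimming array with opposite sign, and simulated unchanged arrays gave -0.49 and -0.47. The covariance was -0.224 and the simulated covariance -0.0236. With the 2 ratios of each gene taken from 2 different probes, over 5365 genes, r was -0.49 and rho -0.29. Genes are not independent replicates, and part of the excess may come from the shared array, which could not be split.

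Of the 710 genes higher with swimming, 546 were within 2-fold of the nonswimming array on the Chlorella array, 124 were still at least 2-fold higher and 40 were at least 2-fold lower. Of genes higher in both, independent lists would share 14.6 and simulated unchanged arrays 0.3. Of the 141 genes lower with swimming, 49 were also lower on the Chlorella array, against 2.0 for independent lists and 0.2 in simulated unchanged arrays. Independent lists leave out the shared nonswimming array and the simulation leaves out the effects, so part of each excess may come from that array. For these 2 ratios r across genes was 0.32, against 0.50 in simulated unchanged arrays and 0.155 with the ratios of each gene from 2 different probes, and the covariance was 0.0760 against a simulated 0.0247.

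**Figure D3:**
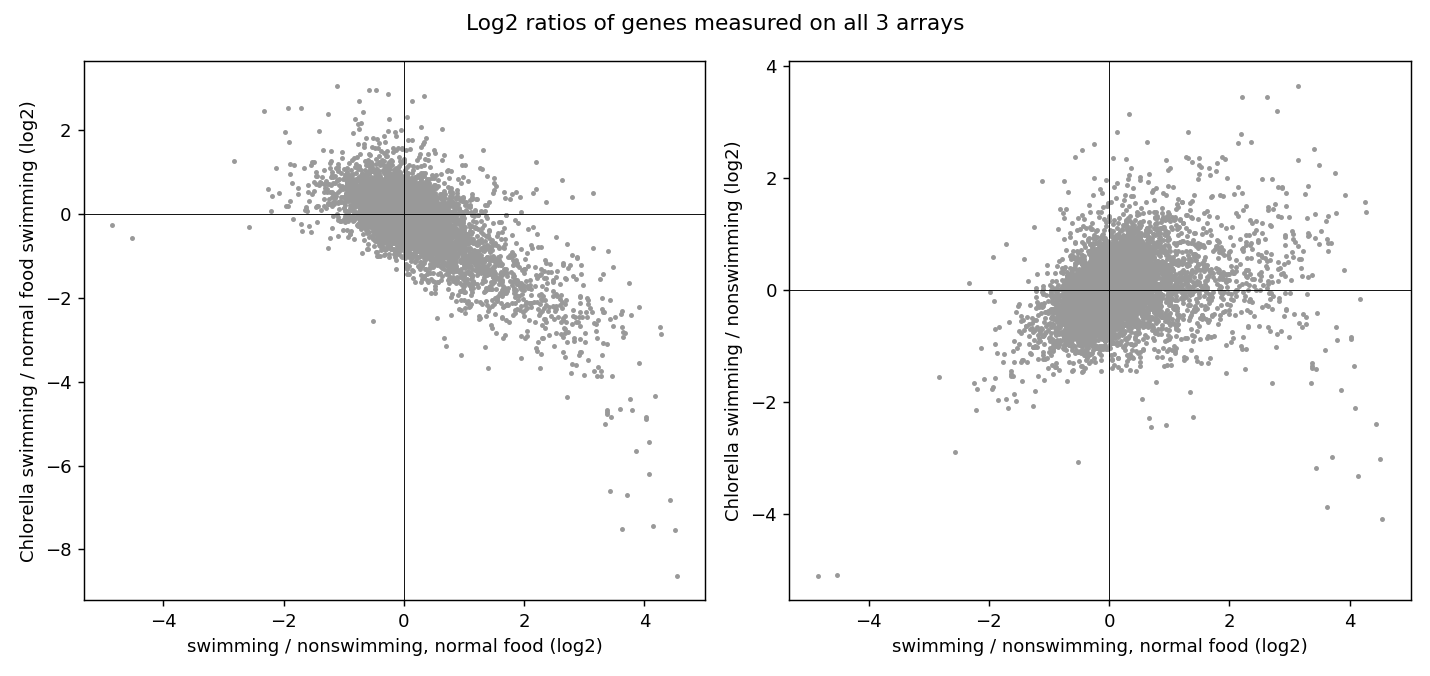
Log2 ratios of the 15269 genes measured on all 3 arrays, 1 point per gene. The horizontal axis is swimming over nonswimming on normal food, and the vertical axis is Chlorella swimming over normal food swimming (left, r = -0.70) or over nonswimming (right, r = 0.32).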

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

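No paired analysis was possible because each group had 1 array of pooled RNA and no result came from a test. Genes without other tissues' lists were counted as an alternative chosen after seeing the data. The direction of the split between higher and lower genes was the same under all alternatives run, but the counts moved with the treatment of dim probes. In swimming against nonswimming (805 higher and 167 lower), normexp gave 387 and 42, no filter 2104 and 1255, the stricter filter 532 and 75 and the authors' values 518 and 110, and median centring gave 276 lower. In Chlorella against normal food in swimming (212 and 754), normexp gave 51 and 301, no filter 1233 and 1998, and the stricter filter and the authors' values gave 117 and 139 higher. In Chlorella swimming against nonswimming (318 and 228), normexp gave 92 and 57, no filter 1395 and 1266, the stricter filter 211 and 136, and the authors' values 194 higher. The filters and the authors' values hold other numbers of genes, the offset of normexp shrinks ratios of dim genes by construction, and median centring moves all genes alike. All genes past the 2-fold rule also passed the 95% limit of the scanner error. The correlation of the swimming and Chlorella ratios was -0.49 from 2 different probes, over fewer genes, and between -0.71 and -0.65 under the other alternatives. Between 20 and 29, 25 and 32, and 20 and 24 lists lay outside their random ranges in the 3 comparisons. Between 57.0% and 60.4% of probes were well above background, and dimmer ones gave no ratio.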

Other observations

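Tests written after their result was seen were those of blood in the vessels, of the share of non-muscle RNA and of a difference only of the swimming array, and the lists of other tissues were written after a first look at the data. Of these lists, swimming against nonswimming, kidney had a median log2 ratio of 2.62, spleen and lymph node stroma 0.79, marrow progenitors and precursors 0.38 and heart 0.35, all above their random ranges. Adrenal (0.28), intestine (0.08), bone and cartilage cells (0.07) and brown fat (0.05) lay inside theirs, and liver (-0.45) lay below. The brown fat list held neither Ucp1 (4.25) nor Cidea (2.80), so its median cannot decide on brown fat. The bone and cartilage list likewise lacked Mepe (2.26). Pancreas and brain had 4 measured genes each and were not ranked. In Chlorella swimming against nonswimming liver (-0.65) and bone and cartilage cells (-0.25) lay below their random ranges, and kidney (0.42) and heart (0.32) above. In Chlorella against normal food in swimming kidney (-2.05), spleen and lymph node stroma (-0.42), bone and cartilage cells (-0.40) and liver (-0.15) lay below. Skin genes were highest on the nonswimming array, where Lor had a signal of 392.5 against 14.09 and 9.498 on the swimming and Chlorella arrays and Krt5 had 283.2 against 12.74 and 6.882, and skin RNA in the nonswimming pool was not weighed and stays open.

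Neutrophil, B cell and erythrocyte genes were higher on the swimming array than on either other array. Blood left in the vessels cannot be told apart by the cell cycle list, whose median was 1.65, since its dividing cells and the blood cell genes need not have 1 source. Bone marrow RNA in the swimming pool is a candidate explanation: the marrow progenitor and precursor list, 28 of 38 genes measured, had a median of 0.38, above its random range of -0.15 to 0.12 but under the bound of 0.5, so for the leukocyte genes entry of mature leukocytes cannot be told apart from marrow by it. In Chlorella against normal food in swimming the same list had a median of 0.01, inside its random range of -0.07 to 0.22, with 11 of 22 genes below 0, and with members at their bound the medians were 1.06 and -1.26, values looked at afterwards. The list shares 8 genes with other lists, and its brightest members, Urod, Cd34, Fech and Alad, had ratios of -0.02, -0.53, -0.05 and 0.07 and are not particular to marrow. The spleen and lymph node stroma list had a larger median of 0.79 over 10 genes, and RNA of these organs was not weighed. An effect of swimming on muscle stays open and untested.

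Kidney genes were higher on the swimming array, with 24 of 27 measured genes at least 2-fold higher, and 27 of the 45 on the array were well above background on the nonswimming array too. A broad gain of dim non-muscle transcripts is argued against by the pooled liver, brain, intestine, adrenal and pancreas genes, whose median was -0.18. Of the 49 measured, 27 were liver genes, and without these, an alternative chosen after seeing the data, the median of the other 22 was 0.14, inside its random range of -0.16 to 0.22 and far below that of kidney. Kidney RNA in the swimming pool may account for it, since the kidney list's median was 2.62 and no other tissue's list reached it: among the brightest members, chosen by signal, Kap had signals of 1519, 9655 and 1800 on the nonswimming, swimming and Chlorella arrays, and Dnase1 185.1, 1677 and 264.8, while Egf, also in the list, had a ratio of 0.14. How such RNA would have entered was not tested, and a response to swimming stays open.

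Glucocorticoid-responsive genes were higher on the Chlorella array than on both others. A lower share of non-muscle RNA is argued against, since their median exceeded that of fast-fibre genes by 0.58, and so is a difference only of the swimming array, since the median against the nonswimming array was also 0.58. Another clock phase at sampling cannot be told apart. Nr1d1 differed by 0.47 ± 0.20 and Arntl by 0.37 ± 0.20, too near the bound of 0.5 for their error. Dbp (-0.32) and Per3 (-0.06) differed the other way, and Npas2 was not well above background on both arrays. Such a phase was expected to move Arntl opposite to Per1, Dbp and Nr1d1. Of these only Dbp had the opposite sign, while Per1, also in the glucocorticoid list, differed by 0.56 ± 0.20. Handling at sampling and an effect of Chlorella stay open as untested hypotheses, with 1 pool per group.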
